A study of Mus musculus with 9 samples.

How the data were processed

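Total RNA from snap-frozen livers of 9 mice was hybridized to Illumina mouse bead arrays as biotin-labelled cRNA, per the labels' protocols, with 1 array per liver. Per the labels, 4 mice were wild-type controls and 5 lacked LTβR and received etanercept, and the value "surgery date" gives a day number for each mouse. The deposited non-normalized file holds, per the file headers, a mean bead signal (intensity) and a detection p-value for each of 45281 probes and each array; the values lie on the raw intensity scale with no step between arrays. The authors' own normalized values are also used, as an alternative. Per the submitters' processing notes the tool was Partek (version not stated), and from their range these deposited values are on a log2 scale. Their column medians lie between 6.77 and 6.80 and their column means are equal at 7.29. The columns were thus made alike by a step that is not stated, and these values do not tell centring or scaling from quantile normalization. In a fit with group and day, the day coefficients of these values were at most 0.0001 for days 2, 4 and 5 against day 1 and 0.0512 on average (absolute) for day 3, so surgery day had been removed in some way; how is not stated. All 27 value columns were used.

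Signals were background-corrected with limma neqc, with the negative control level inferred from the detection p-values (steps of 1/936, offset 16), then quantile-normalized and put on the log2 scale. Probes with a detection p under 0.05 on at least 4 arrays were kept (15687). For each gene the probe with the highest mean was used, which left 11559 features, 9319 with a gene symbol and 2240 probes without one. Gene symbols came from the platform annotation (34885 probes with 1 symbol, 10378 with none, 18 with several), and 34807 probes were matched by Entrez gene ID to a RefSeq table of GRCm38.p6.

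Groups were compared with limma (lmFit and eBayes, two-sided, no covariates), and a Benjamini-Hochberg adjusted p under 0.05 was the threshold. Gene lists were tested with limma camera at a preset inter-gene correlation of 0.01, with adjustment over the 38 lists that had at least 5 measured genes; 4 of the 42 lists had fewer. Each called list is also given with an estimated correlation. All lists were also tested with limma fry and with an exact permutation test over the arrays of the list score, and these are given as counts and for single lists. The score is the mean log2 deviation of the members from each gene's mean. The tools were R 4.3.3, limma 3.58.1 and Python 3.11.15.

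The comparison, filters, lists, alternatives and rule for named genes were fixed before the data were examined. Named were the TNF and lymphotoxin genes and Ltbr, 8 genes tied to liver regeneration, and genes past the threshold, or, where fewer than 5 pass as here, the 10 genes with the smallest p in each direction. Probes without a symbol and clone names were left out of these 10, as the rule states for genes past the threshold. The 17 called lists were the ones described, and for each the 3 members with the smallest p were named, where the rule allows up to 4. Log2 differences are KO minus control, and SD is over arrays.

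The surgery day numbers pair arrays of both groups on 3 days, per the labels. Deviations from the group means of same-day arrays correlated, across genes, at 0.17 on day 1, -0.41 on day 2, -0.56 on day 5 and 0.34 for the KO livers of day 4, and the consensus correlation within days was -0.09. Genes are not independent replicates. Day as a block and as a random effect, slide as a term, each slide alone, each array left out, other normalizations and filters, other variance models and thresholds were run as alternatives. Further ones were added after the data were seen: the fit without KO 4 from background correction on, the authors' values with the day block, the day block without KO 4, the exact permutation of list scores, and camera with an estimated correlation without KO 4 or with the day block.

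The fit was tested on simulated data with the same group sizes and 200 planted genes in each of 20 runs. Each gene was drawn independently, with its mean and SD from the real arrays. Correlation between genes, day differences and a dim array were not simulated, so the rates hold for independent genes only. Differences of 0.5, 1, 2 and 3 on the log2 scale were recovered in 1.1%, 21.8%, 74.8% and 92.5% of cases, and 3.94% of calls were false. With nothing planted, at most 1 gene and 1 list were called in a run, while other splits of the real arrays gave a median of 5 lists (highest 16). Lists with a planted shift of 0.5 were called in 92.5% of cases.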

Results

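Gene expression was measured on Illumina bead arrays in 9 mouse livers taken 12 h after partial hepatectomy, an operation that removes part of the liver and sets off its regrowth. The 4 control livers (control 1 to control 4) came from wild-type mice. The 5 others (KO 1 to KO 5) came from mice that lack the lymphotoxin β receptor (LTβR, gene Ltbr) and that had received etanercept 24 h before surgery. Etanercept is a TNF receptor fusion protein that binds TNF and lymphotoxin α. The replicate numbers only name the animals. Genotype and drug changed together, the labels do not state what the control mice received, and no unoperated liver was measured, so each difference belongs to the combination. Mean bead signal lay between 336 and 438 intensity units on 8 arrays and was 143 on KO 4. Probes with a detection p under 0.05 numbered 13926 to 16186 on those 8 arrays and 9493 on KO 4, out of 45281. The number of arrays limits the precision: the median standard error of a group difference was 0.31 on the log2 scale.

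**Figure D1:**
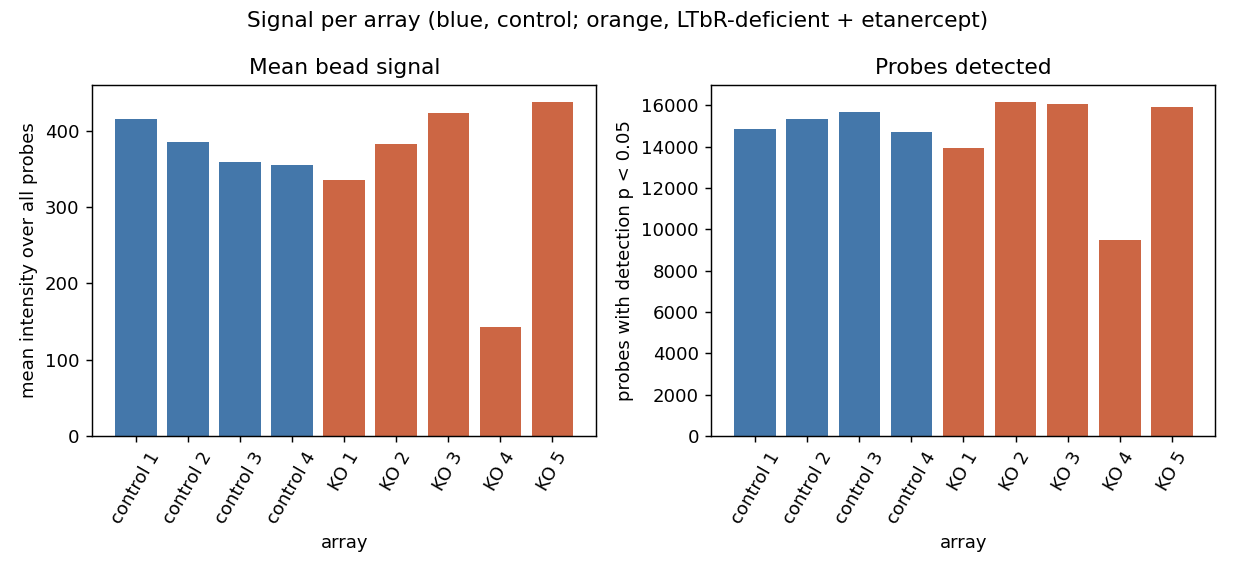
Mean bead signal over all probes (left, intensity units) and number of probes with a detection p under 0.05 (right) for each array, blue for the 4 control livers and orange for the 5 LTβR-deficient, etanercept-treated livers. KO 4 stands apart with a mean of 143 and 9493 probes detected; the other arrays lie at 336 to 438 and 13926 to 16186.

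The comparison between the groups asks which liver transcripts differ early in regeneration between LTβR-deficient, etanercept-treated mice and wild-type controls. Acta2, which encodes smooth muscle α-actin, was the 1 gene of 11559 tested features that passed the threshold. Its normalized log2 expression was 11.49 ± 0.17 (SD, n = 5) in the KO livers and 9.81 ± 0.17 (SD, n = 4) in the controls. The difference was 1.68 ± 0.20 (SE), or 3.21-fold, with a limma adjusted p of 0.0421, and all 5 KO livers lay above all 4 controls. Acta2 (Entrez gene 11475) lies on chromosome 19 from 34240336 to 34255585 in GRCm38.p6. When its probes were fitted one by one, the strongest ones differed by 1.68 and 2.24 with an adjusted p of 0.0543 each, and the weaker ones by 1.22 and 0.31.

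By limma, 1 gene was higher and 0 were lower in the KO group, while 473 had an unadjusted p under 0.05 (190 higher, 283 lower) against 578 expected by chance. With surgery day as a block, Acta2 differed by 1.63 with an adjusted p of 0.948, and 0 genes passed in limma (175 at an unadjusted p under 0.05, 3 residual degrees of freedom). Within slide 1 and slide 2 Acta2 differed by 1.58 and 1.77, and within surgery days 1, 2 and 5 by 1.75, 1.85 and 1.29. Leaving out any single array other than KO 4 ended the call, with adjusted p from 0.108 to 0.291; without KO 4, 4 genes passed.

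Ltbr (Entrez gene 17000, chromosome 6, 125306571 to 125313885), the deleted gene, was read by 1 probe. Its log2 expression was 5.93 ± 0.71 (SD, n = 5) in the KO livers and 6.70 ± 0.30 (SD, n = 4) in the controls. The difference of -0.78 ± 0.35 (SE) did not pass (limma adjusted p = 0.931), and the probe was detected in 4 of 5 KO livers and 4 of 4 controls. KO 4, the dim array, read 4.87 against 5.69 to 6.77 in the other KO livers, and without it the difference was -0.51. Whether this probe lies inside the deleted part is not known, so its value checks no label. In the authors' values the Ltbr difference was -0.48 with an adjusted p of 0.00402; with surgery day as a block in those values it was -0.46 and the call was lost (adjusted p = 0.783). The TNF receptor genes Tnfrsf1a and Tnfrsf1b differed by -0.14 ± 0.35 (SE) and -0.26 ± 0.57 (SE), and neither passed; both differences turned positive with median scaling, with cyclic loess, on slide 1 alone and without KO 4 (0.062 and 0.276 in the last), and the tested probes of Tnfrsf1a differed in sign. Tnf, Lta and Ltb were detected on too few arrays to be tested, as were Il6, Myc, Ccna2 and Cyp7a1 among the genes tied to liver regeneration.

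**Figure D2:**
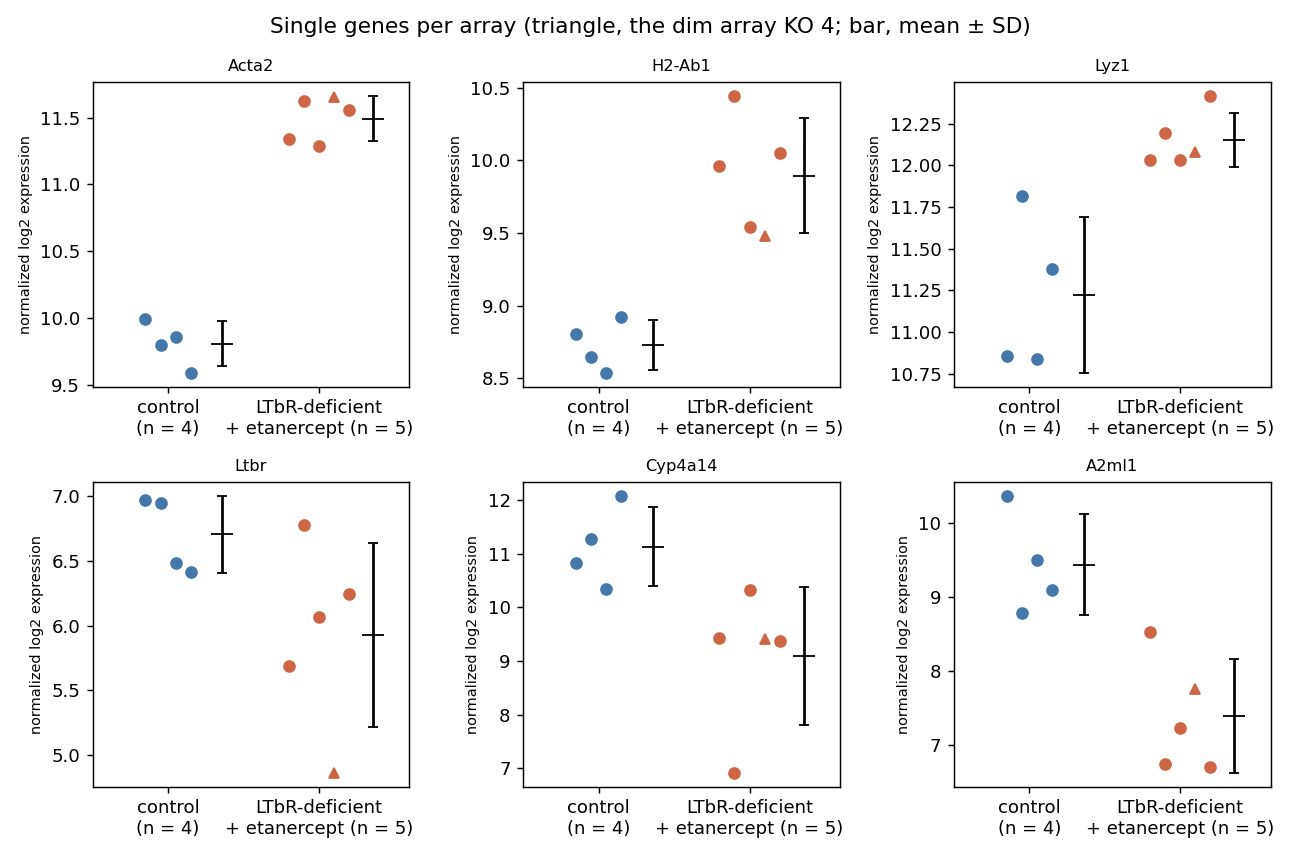
Normalized log2 expression of 6 genes on each array, blue for the controls (n = 4) and orange for the KO livers (n = 5), with the triangle for KO 4 and the bars at mean ± SD. Acta2 separates the groups at 11.49 against 9.81 and passed the test; the other 5 genes, chosen after their values were seen, did not pass, and Ltbr overlaps between the groups.

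Beyond Acta2, the genes with the smallest p in each direction are given as values, since they did not pass. Higher mean values in the KO livers were found for H2-Ab1 (1.17 ± 0.25, SE) and H2-Eb1 (1.09 ± 0.22, SE), both MHC class II genes, each with an adjusted p of 0.614. The others in this direction were Tagln (0.86), a smooth muscle cytoskeletal gene, the lysozyme gene Lyz1 (0.93), Lgals3 (0.69), which encodes galectin 3, Ctla2b (1.14), Ankrd1 (1.17), Apobec1 (1.20) and Ahnak (0.86). For Ahnak, 1 tested probe had the opposite sign (-0.71), and for Lyz1 only the probe used was detected on any array. Lower mean values in the KO livers were found for A2ml1 (-2.05 ± 0.43, SE; adjusted p = 0.614), Depp1 (-2.07), Cyp4a14 (-2.04), a fatty acid hydroxylase, and Igdcc4 (-1.62). Plekha6 (-1.36), Ppm1k (-1.27), Mtnr1a (-1.23), Flvcr2 (-1.11) and Socs3 (-1.05), an inhibitor of cytokine signalling induced by STAT3, followed. The KO and control arrays overlapped for Ankrd1, Ahnak, Igdcc4, Flvcr2, Depp1 and Ppm1k and did not for the others. Lama1 was detected on all 4 control arrays and on none of the KO arrays, and was at least 1.28-fold higher in the controls. With array quality weights, which gave KO 4 a weight of 0.142 and KO 5 one of 4.92, H2-Ab1, H2-Eb1 and A2ml1 passed (adjusted p 0.0198, 0.0291 and 0.0198).

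Gene lists fixed before the data were examined were tested with limma camera, and 17 of the 38 lists with enough measured genes passed, 5 higher and 12 lower in the KO livers. Over all genes tested, 0 of the 463 members of these 17 lists passed in limma, and 49 had an unadjusted p under 0.05; adjusted over the list alone, 4 members of the MHC class II list passed and 0 of the other 16 lists. With an inter-gene correlation estimated from the data, the call held for the MHC class II list and was lost for the other 16. In an exact permutation test of the list scores of the arrays, 0 lists passed after adjustment and 4 had an unadjusted p under 0.05 (two-sided). This test could hardly call a list: a single list at its smallest possible p, 0.00794, stands at 0.302 after adjustment. Its adjusted outcome therefore decides little. Before adjustment that limit does not apply. The 4 lists under 0.05 by exact permutation were MHC class II (0.00794), fatty acid oxidation (0.0317), male-biased (0.0317) and macrophage (0.0397). The other called lists missed 0.05 even so, among them G1 to S (0.135), G2 and mitosis (0.214) and ribosome biogenesis (0.341). Without KO 4, 17 lists passed, 16 of them the same.

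MHC class II genes, which present antigen to T cells, rose together in the KO livers: all 9 measured members had a positive difference, with a mean of 0.74 on the log2 scale (limma camera adjusted p = 4.69e-07; 0.0471 with an estimated correlation). The list score was 0.33 ± 0.19 (SD, n = 5) in the KO livers and -0.41 ± 0.22 (SD, n = 4) in the controls without overlap, with an exact permutation p of 0.00794, the smallest these arrays can give (adjusted 0.302). Cd74, the invariant chain, differed by 1.18 ± 0.43 (SE), next to H2-Ab1 and H2-Eb1. With an estimated correlation the list did not pass without KO 4 (mean 0.71, adjusted p = 0.171) or with surgery day as a block (mean 0.65, adjusted p = 0.662). Markers of Kupffer cells and other macrophages rose by a mean of 0.45, with 17 of 19 members positive (limma camera adjusted p = 4.62e-06; 0.242 with an estimated correlation). Among them Marco, a scavenger receptor, differed by 1.10 ± 0.35 (SE) and Vsig4, a complement receptor of Kupffer cells, by 0.64 ± 0.22 (SE). Lyz1 differed by 0.93 ± 0.25 (SE), by the only probe of it that was detected. Hepatocyte markers had a mean of -0.16, which did not pass (adjusted p = 0.294). They passed as lower under 4 of 37 alternatives, among them median scaling (-0.33, adjusted p = 0.00304).

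**Figure D3:**
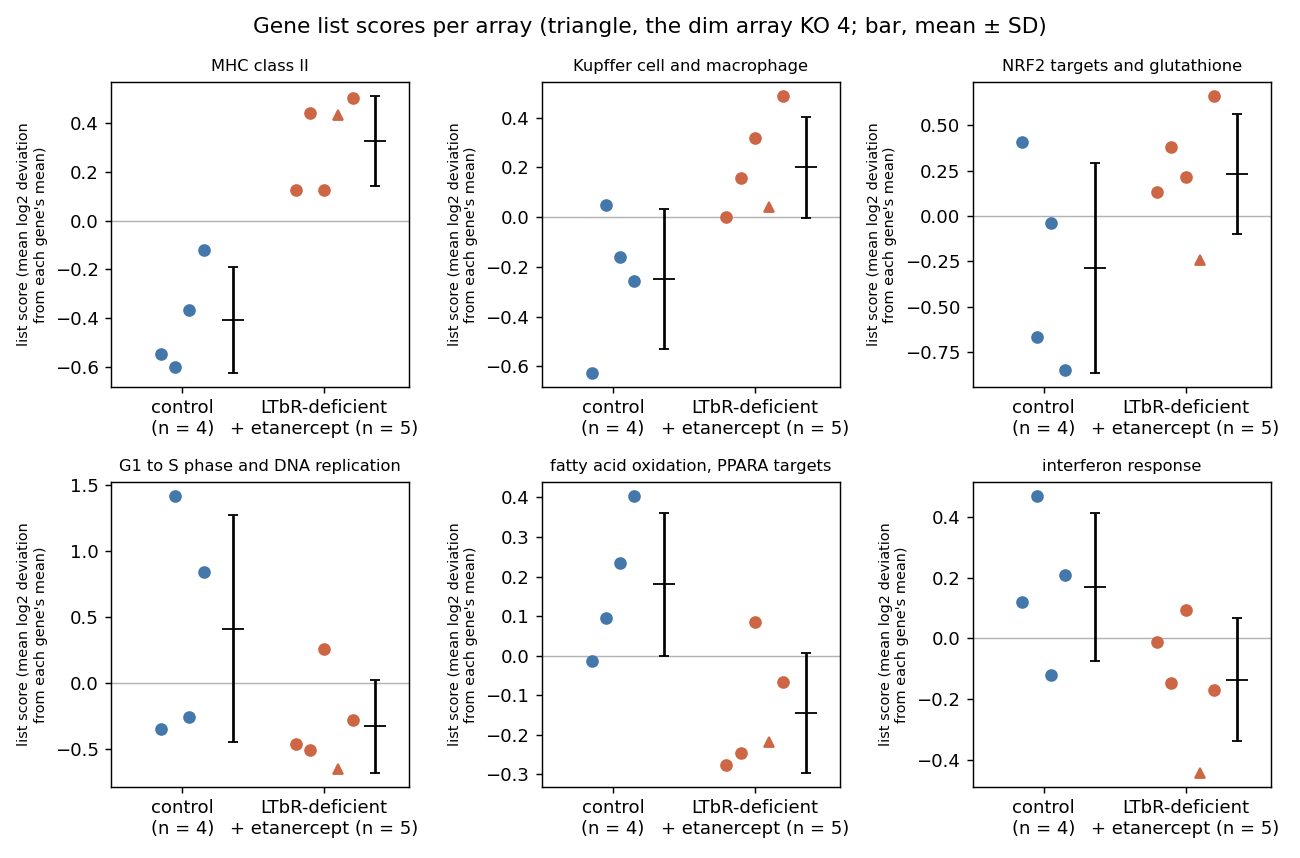
List score of each array (mean log2 deviation of the members from each gene's mean over all arrays) for 6 of the called lists, chosen for display after their values were seen, blue for controls (n = 4), orange for KO livers (n = 5), triangle for KO 4, bars at mean ± SD. The MHC class II scores do not overlap (0.33 against -0.41), while the G1 to S scores of the controls range from -0.35 to 1.41.

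Genes of DNA replication and the G1 to S transition fell in the KO livers by a mean of 0.74 on the log2 scale, with 33 of 35 members negative (limma camera adjusted p = 9.15e-09; 0.347 with an estimated correlation). The replication factor genes Mcm10 and Gins2 differed by -1.76 ± 0.68 (SE) and -0.63 ± 0.25 (SE), and E2f1, a transcription factor of S phase entry, by -1.55 ± 0.64 (SE). The control scores were uneven, with control 2 at 1.41 and control 4 at 0.84, but control 1 at -0.35 and control 3 at -0.26, inside the KO range of -0.65 to 0.25. Without control 2 the list mean was -0.41. Genes of G2 and mitosis fell by a mean of 0.40, with 14 of 15 members negative (adjusted p = 0.00209; 0.473 with an estimated correlation), and this call was lost without control 2 (-0.12, adjusted p = 0.356). Mad2l1, Aurka and Cdc20, which act in mitosis, differed by -0.77, -0.97 and -0.57. Cyclin D1 (Ccnd1) differed by -0.76 ± 0.50 (SE) and the cell cycle inhibitor Cdkn1a by 1.24 ± 0.56 (SE), both with an adjusted p of 0.931; the Ccnd1 difference was 0.0076 on slide 2 alone.

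Genes of fatty acid oxidation and PPARA targets fell by a mean of 0.32, with 26 of 36 members negative (limma camera adjusted p = 0.000505; 0.347 with an estimated correlation). Cyp4a14 differed by -2.04 ± 0.60 (SE), Bdh1, an enzyme of ketone body metabolism, by -1.11 ± 0.40 (SE), and Crat, carnitine acetyltransferase, by -1.04 ± 0.37 (SE). Genes of glucose and amino acid metabolism fell by a mean of 0.42 (median -0.25), with 30 of 36 negative (adjusted p = 0.00209; 0.433 with an estimated correlation). Ppp1r3b and Ppp1r3c, regulators of glycogen synthesis, differed by -1.74 and -1.68, and Fbp1, an enzyme of gluconeogenesis, by -0.69. With surgery day as a block this list stood at -0.09 (adjusted p = 0.939), with the block and KO 4 left out at 0.18 (adjusted p = 0.00696), without control 3 at -0.29 (adjusted p = 0.174) and without control 1 at -0.64. Genes of fatty acid and triglyceride synthesis fell by a mean of 0.25, with 17 of 26 negative (adjusted p = 0.0261; 0.347 with an estimated correlation), among them Fads2 (-0.86), Nr1h3 (-0.79) and Mlxipl (-0.61). That call was lost with the day block (-0.26, 0.150) and without KO 4 (-0.17, 0.0742), KO 1 (-0.22, 0.1001) or control 3 (-0.22, 0.0624), each with the list mean and its adjusted p.

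Genes of bile acid synthesis and transport fell by a mean of 0.21, with 22 of 28 negative (limma camera adjusted p = 0.0136; 0.347 with an estimated correlation). Klb, a co-receptor that represses bile acid synthesis, differed by -1.01, the sterol transporter gene Abcg5 by -0.57 and Amacr by -0.53. The day block gave -0.14 for the list (adjusted p = 0.344). Both sex-biased lists of liver genes fell. The female-biased list fell by a mean of 0.57, with 6 of 9 members negative (adjusted p = 0.0208), and the male-biased list by 0.24 (median -0.15), with 17 of 19 negative (adjusted p = 0.0283); both had an adjusted p of 0.347 with an estimated correlation. Cyp17a1 (-1.27) and Acot3 (-0.98) stood in the former beside Cyp4a14, and Nudt7 (-0.88), Cyp7b1 (-0.46) and Cyp2u1 (-0.39) in the latter. The day block gave adjusted p of 0.247 and 0.190 for these lists. The female-biased call was lost without KO 5 (-0.54, 0.0567), and the male-biased one without control 3 (-0.25, 0.0822), control 4 (-0.17, 0.0740), KO 3 (-0.24, 0.0999) or KO 5 (-0.21, 0.133), each with the list mean and its adjusted p.

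Genes of the acute phase response downstream of IL-6 and STAT3 fell by a mean of 0.27, with 29 of 41 negative (limma camera adjusted p = 0.00724; 0.347 with an estimated correlation). Socs3 differed by -1.05 ± 0.31 (SE), and the serum amyloid genes Saa4 and Saa1 by -2.51 ± 0.83 (SE) and -1.05 ± 0.54 (SE); without KO 4, Saa1 differed by -0.67. Cd14, a co-receptor for bacterial lipopolysaccharide and a member of the same list, differed by 1.93 ± 0.73 (SE). With the day block the list stood at -0.30 (adjusted p = 0.0543). Interferon response genes fell by a mean of 0.31, with 26 of 38 negative (adjusted p = 0.00139; 0.347 with an estimated correlation). Irgm2, Irf9 and Stat2 differed by -1.46, -1.13 and -0.65, and Irf9 by -0.74 without KO 4. Among the members detected on all 9 arrays at a detection p under 0.01, the list mean was 0.05 (adjusted p = 0.784), and with the day block and without KO 4 it was -0.12 (adjusted p = 0.151). Complement and coagulation genes fell by a mean of 0.16, with 35 of 43 negative (adjusted p = 0.0261; 0.4999 with an estimated correlation). C4bp (-0.58) and Klkb1 (-0.51) were lower and Cfp, properdin, was higher (0.66), none of them past the threshold. That call was lost with the day block (-0.15, 0.393) and without control 2 (-0.089, 0.295), control 3 (-0.12, 0.183), KO 1 (-0.15, 0.0924) or KO 5 (-0.15, 0.112), each with the list mean and its adjusted p. The mean was -0.28 without control 1 and -0.11 without KO 4.

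Immediate-early growth response genes rose by a mean of 0.37, with 23 of 33 positive (limma camera adjusted p = 0.000505; 0.347 with an estimated correlation). Ccn2, which encodes connective tissue growth factor, differed by 1.76 ± 0.56 (SE), Klf6 by 1.32 ± 0.51 (SE) and the phosphatase gene Dusp1 by 0.78 ± 0.31 (SE). The list mean was 0.23 without control 2 and -0.42 within surgery day 5, and with the day block and without KO 4 it was 0.11 and did not pass (adjusted p = 0.192). NRF2 targets and glutathione genes rose by a mean of 0.52 (median 0.19), with 26 of 36 positive (adjusted p = 0.000505; 0.378 with an estimated correlation). The glutathione transferase genes Gsta1 and Gsta2 differed by 3.46 ± 1.13 (SE) and 2.98 ± 1.21 (SE), and Cbr3, a carbonyl reductase, by 1.89 ± 0.78 (SE). In the controls Gsta1 ranged from 7.16 in control 4 to 13.74 in control 1, while the KO livers lay between 12.72 and 13.93. Without control 4 the list mean was 0.33. Ribosome biogenesis genes rose by a mean of 0.22, with 29 of 36 positive (adjusted p = 0.000673; 0.425 with an estimated correlation). Nle1 (0.83) and Mybbp1a (0.63) were higher and Tsr1 lower (-0.87), none past the threshold, and with the day block the list turned to -0.05 (adjusted p = 0.939). The list mean was 0.36 without KO 4, 0.11 without KO 2 and 0.12 without KO 5. Genes of the unfolded protein response fell by a mean of 0.26, with 19 of 27 negative (adjusted p = 0.0305; 0.347 with an estimated correlation). The endoplasmic reticulum genes Creld2 and Hsp90b1 differed by -1.43 and -0.47, and Trib3 by 1.11; without KO 4, Creld2 differed by -0.91. The call was lost without control 3 (-0.27, adjusted p = 0.0822), control 4 (-0.20, 0.163), KO 1 (-0.21, 0.214) or KO 3 (-0.30, 0.0675), each with the list mean and its adjusted p.

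Within each slide, all 17 called lists kept the sign they had over all arrays. The lists were called on these same arrays, so this agreement is largely built in and is no separate support. Each surgery day below sets 1 array against 1, and on day 2 the KO array is the dim one. Within surgery day 1 (control 4 and KO 1), 17 of 17 kept it, and within day 2 (control 2 and KO 4), 15 of 17. The 2 that turned on day 2 were the macrophage list (-0.0099) and the ribosome biogenesis list (-0.28). Within day 5 (control 1 and KO 3), 5 of 17 did. On that day the G1 to S list differed by 0.60 and the glucose and amino acid list by 0.71, against -0.74 and -0.42 over all arrays, while MHC class II kept 0.68 and the macrophage list 0.94. Day 3 held a control alone and day 4 held KO livers alone, so neither gives a difference.

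With the day block and without KO 4, an alternative added after the data were seen, 12 lists passed. Besides the immediate-early and interferon lists, calls were lost for G2 and mitosis (-0.14, adjusted p = 0.323), ribosome biogenesis (0.069, adjusted p = 0.258), the acute phase response (-0.14, adjusted p = 0.246) and fatty acid synthesis (-0.13, adjusted p = 0.323). They were also lost for the female-biased (-0.35, adjusted p = 0.228) and male-biased lists (-0.18, adjusted p = 0.146), and for bile acid (0.016, adjusted p = 0.809) and complement genes (0.084, adjusted p = 0.230), whose sign turned.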

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

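The tests of the macrophage and MHC class II lists were chosen only after their results were seen, and so was 1 of the versions of the day removal described here. Within each group, each named gene, list score and array measure was examined for an array far from the others (Dixon's ratio). Chance picks about 1 in 20 groups, or 9.7 of the 194 examined, and 8 were picked: 6 among KO livers, 2 of them on KO 4, and 2 among controls.

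Cyp4a14 stood at a log2 expression of 6.91 in KO 2, against 9.38 to 10.32 in the other KO livers. Irf9 stood at 5.59 in KO 4, against 7.36 to 7.91. Lgals3 stood at 11.31 in KO 4, against 10.86 to 10.94. In KO 3, Crat stood at 7.19 (5.64 to 6.00 in the other KO livers), Klb at 6.35 (5.02 to 5.30) and Dusp1 at 11.33 (12.34 to 12.54). Cyp2u1 stood at 5.12 in control 4, against 4.96 to 4.97 in the other controls, and the stellate cell list score stood at 0.208 in control 3, against -0.045 to -0.035.

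The count of genes and the count of lists were compared with those of other splits of the 9 arrays into 4 and 5 (100 of 126 drawn, the real one included). For genes, 7 of the 100 splits gave at least the 1 gene of the real split, so chance cannot be excluded; the highest other split gave 535 and 93 gave none in limma. The split with 535 genes put control 1, control 4, KO 1 and KO 4 on one side. These 4 arrays had the fewest probes detected, at 9493 to 14868 against 15323 to 16186 on the others. Whether detection underlies the 535 genes was not tested. For lists, 1 of 100 splits, the real one, gave as many as 17. The highest other gave 16 and the median of the others was 5. This argues against chance for that count with the preset correlation. It does not exclude chance, since another split came close and not all splits were drawn. The split with 16 lists also gave 294 genes: it exchanges control 1 and KO 3, the livers of day 5. Of the 28 other drawn splits that part as many same-day pairs as the real one, 1 gave as many genes and 0 as many lists. The split by slide gave 0 genes and 1 list. With surgery day as a block, 0 genes (175 at an unadjusted p under 0.05, limma) and 10 lists passed.

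In the authors' values 1071 genes passed, and in the re-normalized ones 1. Removing surgery day around the groups from the re-normalized values and testing without a day term gave 170 genes for the real groups, and a median of 1579 (highest 9358) over the other groupings of the same arrays. Over those that part as many same-day pairs as the real one, the median was 552 (highest 6402), and 18 of 28 called as many. Of 95 groupings, 68 called as many as the real one, which argues against reading the count as a group difference; removing a batch and then testing as if it had not been fitted may therefore account for part of it. The ratio of 170 to 1071 genes, 0.159, leaves room for the authors' other normalization steps, which are open. A first version that left day 3 as it was gave 1 gene for the real groups and a median of 22. Removal over all days was chosen after both were seen, for the wording of the prediction and for control 3. There the authors' values follow it more closely (a correlation across genes of 0.82 against 0.57). In control 4 (0.875 against 0.893), KO 4 and KO 5 they follow the first version slightly more closely. The other arrays follow removal over all days more closely. Day 3 kept a coefficient of 0.0512 on average (absolute) in the authors' values, so neither version is known to be their step.

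Macrophage and MHC class II genes were higher in the KO livers. A lower share of hepatocyte RNA would raise other cell types alike. For MHC class II the shift exceeded that of the endothelial and stellate lists by 0.685 and 0.742 (exact permutation p = 0.00794 and 0.0159, two-sided, surgery day not considered). These tests, and those of the macrophage list below, used the median deviation of the members on each array, not the mean. The list was picked for its difference in these same arrays, so these p-values understate chance. Over all arrays the endothelial and stellate means were -0.0020 and -0.04 against 0.74 for MHC class II. With the main filter this argues against a lower hepatocyte share for that list. With detection required on all arrays, the stellate list passed at 0.34 (limma camera adjusted p = 0.0403) and the endothelial mean was 0.086. Hepatocyte markers passed as lower under 4 of 37 alternatives. A lower hepatocyte share is therefore not excluded. Within day 1, however, the stellate list differed by 0.27 and MHC class II by 0.25 (-0.034 against 1.04 on day 2, -0.27 against 0.68 on day 5). For the macrophage list the exact permutation p was 0.0476 and 0.0635, so a lower hepatocyte share cannot be told apart from a change in macrophages at this number of arrays. The dim array KO 4 as the source is argued against, since without it the median difference of the MHC class II list kept 0.799 and that of the macrophage list 0.972 of its value. A change in cell number or in expression per cell, from LTβR loss, etanercept or both, stays open and may underlie the pattern.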

How the results depend on the processing

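The tests without KO 4 from background correction on, those of the authors' values with the day block, those with the day block without KO 4, the exact permutation of list scores, and the estimated correlation without KO 4 or with the day block were chosen only after the results were seen. So were the 7 lists that had not passed and are followed here.

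Acta2 was higher in the KO livers under all 31 alternatives run (1.36 to 1.77, adjusted p 0.000538 to 1.00), stayed past the threshold under 12 and missed it under 19. The G1 to S, MHC class II, macrophage and fatty acid oxidation lists kept their sign under all 37 alternatives run and passed under all with the preset correlation, except that no list passed where a difference of at least 1 was also required. The differences within a single surgery day are not among these alternatives, and there G1 to S (0.60) and fatty acid oxidation (0.098) turned sign on day 5 and the macrophage list (-0.0099) on day 2. Under exact permutation and under the estimated correlation without KO 4 or with the day block, 0 lists passed. The exact permutation could hardly call a list after adjustment, and the calls it lost are counted in the next sentence. Of the values of named genes under alternatives, 18 turned sign, 44 passed where the reported one did not and 19 no longer passed; of those of lists, 79 turned sign, 167 no longer passed and 7 newly passed. With the day block, 8 lists lost their call, as given with each in the report, sterol biosynthesis newly passed, and no other call of a list changed. No cause was tested for a change unless stated. Tests within a slide or with the day block have fewer arrays or degrees of freedom. Signal over background limits the dim genes: on KO 4, 9493 probes were detected against at least 13926 elsewhere, Ltbr gave no value where detection on all arrays was required, and Tnf, Ltb and Il6 stayed at background.

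Without background correction, the sign turned for canonical NF-kB 0.010, endothelial 0.0090, stellate 0.034. With median scaling, 5 genes passed (5 higher, 0 lower) and the sign turned for Tnfrsf1a 0.23, Tnfrsf1b 0.11, canonical NF-kB 0.037, non-canonical NF-kB 0.12, stellate 0.016. With cyclic loess, 11 lists passed and the sign turned for Tnfrsf1a 0.063, Tnfrsf1b 0.14, canonical NF-kB 0.069, non-canonical NF-kB 0.078, endothelial 0.0037. In the authors' values, 1071 genes passed (393 higher, 678 lower), 10 lists passed, Ltbr differed by -0.48 and the sign turned for TNF ligands and receptors -0.069, endothelial 0.059, stellate 0.038. Without a detection filter, the sign turned for canonical NF-kB 0.0086. With detection on all arrays, the sign turned for interferon 0.052, canonical NF-kB 0.13, endothelial 0.086, stellate 0.34, adjacent to Ltbr 0.090. With all probes tested, 0 genes passed in limma (577 unadjusted) and the sign turned for TNF ligands and receptors -0.079, canonical NF-kB 0.015, stellate 0.11. With the mean of each gene's probes, 0 genes passed in limma (483 unadjusted) and the sign turned for non-canonical NF-kB 0.019. With slide as a term, 0 genes passed in limma (486 unadjusted) and the sign turned for canonical NF-kB 0.015, non-canonical NF-kB 0.00030. With surgery day as a block, 0 genes passed in limma (175 unadjusted), 10 lists passed and the sign turned for ribosome biogenesis -0.047, TNF ligands and receptors -0.15, endothelial 0.056. With day as a random block, the sign turned for canonical NF-kB 0.016, non-canonical NF-kB 0.010. With the day block and slide, 0 genes passed in limma (165 unadjusted), 11 lists passed and the sign turned for TNF ligands and receptors -0.11, endothelial 0.059, stellate 0.048. On the 3 shared days alone, with the block, 0 genes passed in limma (87 unadjusted), 11 lists passed and the sign turned for ribosome biogenesis -0.047, TNF ligands and receptors -0.15, endothelial 0.056. On slide 1 alone, 0 genes passed in limma (334 unadjusted), 11 lists passed and the sign turned for Tnfrsf1a 0.25, Tnfrsf1b 0.39, endothelial 0.067, stellate 0.19. On slide 2 alone, 0 genes passed in limma (71 unadjusted) and the sign turned for Ccnd1 0.0076, TNF ligands and receptors -0.022, canonical NF-kB 0.084, non-canonical NF-kB 0.17. With array quality weights, 10 genes passed (9 higher, 1 lower) and the sign turned for Tnfrsf1b 0.24, canonical NF-kB 0.12, non-canonical NF-kB 0.19. With a log2 difference of at least 1 required, 0 lists passed, and none could, since no list mean exceeded 0.74 in size. With an estimated correlation, 1 list passed, MHC class II. With fry, 1 list passed, MHC class II. With 8 arrays re-normalized without KO 4, 4 genes passed (4 higher, 0 lower) and the sign turned for Tnfrsf1a 0.060, Tnfrsf1b 0.28, canonical NF-kB 0.047, non-canonical NF-kB 0.078. In the authors' values with the day block, 0 genes passed in limma (514 unadjusted), 10 lists passed and the sign turned for TNF ligands and receptors -0.060, endothelial 0.062, stellate 0.064. With the day block and without KO 4, 0 genes passed in limma (113 unadjusted) and the sign turned for Tnfrsf1b 0.29, Abcg5 0.060, Cyp17a1 0.097, C4bp 0.076, Trib3 -0.37, Ccnd1 0.065, glucose and amino acid 0.18, bile acid 0.016, complement 0.084, TNF ligands and receptors -0.025, hepatocyte 0.11, endothelial 0.012, adjacent to Ltbr 0.042. In that fit 10 of the 17 called lists lost their call, as given in the report, and the glucose and amino acid list passed in the opposite direction. With the exact permutation of scores, 0 lists passed, though its smallest possible p leaves little room after adjustment. With an estimated correlation and without KO 4, 0 lists passed and the sign turned for canonical NF-kB 0.045, non-canonical NF-kB 0.072. With an estimated correlation and the day block, 0 lists passed and the sign turned for ribosome biogenesis -0.047, TNF ligands and receptors -0.15, endothelial 0.056.

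Leaving out each array in turn gave 0 to 4 genes past the threshold, 0 to 4 higher and 13 to 19 lists. Without KO 4 the 4 were Acta2, ILMN_1249975, ILMN_2744657 and ILMN_2744660, without control 4 the only one was ILMN_2633179, and without any other array 0 passed in limma (150 to 1214 unadjusted). Over these fits the differences ranged as follows: canonical NF-kB -0.12 to 0.071, non-canonical NF-kB -0.079 to 0.072, TNF ligands and receptors -0.055 to 0.14, endothelial -0.025 to 0.024, stellate -0.10 to 0.031, Tnfrsf1a -0.43 to 0.062, Tnfrsf1b -0.53 to 0.28. Differences of named genes other than these that moved by over 1.5 times were, without control 2, E2f1 -0.97, Mad2l1 -0.43, Aurka -0.48, Cdc20 -0.28, Fbp1 -0.43 and Cyp17a1 -0.81. Without control 4 they were Mcm10 -1.13, Mlxipl -0.36, Nudt7 -0.58, Cyp7b1 -0.28, Hsp90b1 -0.30 and Cdkn1a 0.82. Ccnd1 was -0.49 without KO 2 and -1.20 without KO 3, and without KO 4 the genes were Ltbr, Irf9, Creld2 and Saa1, as given in the report. The 5 genes with median scaling were probes without a symbol (ILMN_1249975, ILMN_2633179, ILMN_2677207, ILMN_2744657 and ILMN_2744660), and the 10 with array weights were Acta2, H2-Ab1, H2-Eb1, A2ml1, those 5 and ILMN_2704562; they are named after their values were seen. For the differences between settings the cause was not tested.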

Other observations

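The test of genes near Ltbr was chosen only after A2ml1 and Apobec1 had been seen among the top genes, that of its splits after the percentile was known, and the splits without A2ml1, Apobec1 and Depp1 after the splits with them. Stellate cell and fibroblast markers, the list that holds Acta2 and Tagln, did not move as a group: the mean difference over 20 measured members was -0.04 (limma camera adjusted p = 0.978), and 13 were negative. Adjusted over the list alone, Acta2 and Tagln passed, while Lrat, a gene of vitamin A storage in quiescent stellate cells named after its value was seen, differed by -1.01 ± 0.36 (SE; adjusted p = 0.931). With detection required on all arrays the list passed at 0.34 (adjusted p = 0.0403). Extracellular matrix genes had a mean of 0.12 (adjusted p = 0.226), cholangiocyte markers 0.23 (0.180), sinusoidal endothelial markers -0.0020 (0.901), dendritic cell markers 0.071 (0.620), neutrophil markers 0.13 (0.404) and erythroid and platelet markers 0.12 (0.464), each with its adjusted p. Inflammatory monocyte markers (-0.00036, 0.763) and T and NK cell markers (-0.057, 0.978) had 5 measured members each.

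The lists closest to the treatment did not pass. TNF and lymphotoxin ligands and receptors had a mean of 0.030 (adjusted p = 0.817), canonical NF-kB targets -0.0014 (0.868) and the non-canonical NF-kB and LTβR pathway -0.0082 (0.817), and their signs varied with the normalization. The canonical NF-kB list passed with a negative mean under 1 of 37 alternatives (lowest limma camera adjusted p 0.0366), and its sign turned under 18. Sterol biosynthesis genes had a mean of -0.27, with 18 of 20 negative (adjusted p = 0.0518; 0.0259 with surgery day as a block and 0.0276 without KO 4; with an estimated correlation, adjusted p = 0.389, and 0.662 with the block). Liver growth factors (0.13, 0.620), p53 targets and cell cycle inhibitors (0.16, 0.311), hypoxia genes (-0.084, 0.620), apoptosis regulators (-0.039, 0.888), cytochromes P450 (-0.0049, 0.817) and clock genes (-0.033, 0.901) did not pass either. Without KO 4 the means of hypoxia genes (0.017), cytochromes P450 (0.058), inflammatory monocyte markers (0.079), T and NK cell markers (0.019), canonical NF-kB targets (0.045) and the non-canonical pathway (0.072) turned positive. With surgery day as a block the means of cytochromes P450 (0.14), clock genes (0.081), T and NK cell markers (0.034), endothelial (0.056), neutrophil (-0.034) and dendritic cell markers (-0.020) and TNF ligands and receptors (-0.15) turned sign. The camera direction was opposite to the mean for inflammatory monocytes, canonical NF-kB and clock genes, and the median opposite to the mean for the erythroid, non-canonical NF-kB and T and NK lists.

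Of the probes without a gene symbol, 4 with small p are given after their values were seen: ILMN_2744657 differed by 2.88 (adjusted p = 0.129), ILMN_2633179 by 3.06 (adjusted p = 0.246), ILMN_1227679 by -1.26 and ILMN_1222598 by -1.02 (adjusted p = 0.931 each). Their genes are not known here.

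A knockout made in one strain can carry flanking donor DNA, so genes near Ltbr may differ for that reason. The mean absolute moderated t of the 104 measured genes within 10 Mb lay at percentile 99.95 of 10000 random gene sets of like expression, at 98.38 without A2ml1, Apobec1 and Depp1, and at 98.67 without KO 4. Among them, 0 passed in limma and 11 had an unadjusted p under 0.05, against 5.2 by chance. In 3 of 100 splits the excess over other genes was as large (real 0.228, highest other 0.338), but this includes the genes that prompted the test. Without A2ml1, Apobec1 and Depp1, 10 of 100 splits gave as large an excess (real 0.145, highest other 0.302), so chance cannot be excluded. The strain background of the mice was not tested, and flanking DNA and shared regulation of neighbours both stay open. The list of adjacent genes fixed beforehand had a mean of -0.16 (adjusted p = 0.127), and of -0.028 without KO 4 (adjusted p = 0.765). It passed with a negative mean under 2 of 37 alternatives (lowest limma camera adjusted p 0.0249), and its sign turned under 2.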
